A study of Mus musculus with 6 samples.

How the data were processed

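Gene expression was measured by RNA sequencing in organoids grown from wild-type mouse small intestine, cultures of epithelial crypts that form budding structures in a gel matrix. Per the labels' protocols, organoids were exposed for 17 h to the thyroid hormone T3 at 1e-07 M or to its vehicle before RNA was extracted, and the libraries were directional. The labels give 3 libraries per group and do not say whether they came from separate cultures or animals, so p-values measure only the spread between these 6 libraries, which may be technical.

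STAR, Subread and DESeq2 are named in the submitters' processing notes without versions, and the strand setting of the read counting is not given in the sources used here. The build, mm10 (GRCm38), is taken from the column names, per the file headers. The deposited table lists 27179 genes, and the authors' deposited sample columns hold reads per gene scaled between libraries and rounded to whole numbers, a normalized score and not a count. The mean column deposited by the authors equalled the mean of the 6 sample columns to within 0.833 normalized reads in every gene, which is how the scaling was recognised. The authors' deposited table also gives log2 fold changes with standard errors and p-values with adjusted p-values for T3 against vehicle, and gene length and position under other column headings. A second table deposited by the authors holds 5786 genes, all with an adjusted p-value of at most 0.09997 in the authors' comparison.

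Scaled and rounded columns keep a trace of their scaling, because a whole count divided by a size factor leaves gaps or doublings among low values. A likelihood over candidate factors gave factors between 0.914 and 1.0765 for the 6 libraries. On 4 simulated libraries its largest error was 0%, but their true factors were among the candidates, so the error for other factors was not measured. Multiplied by the column totals these factors correspond to an estimated 26100000 to 31100000 reads on genes per library. Reads lost to rounding could not be restored, so no count model was applied. This differs from the test planned for raw counts, and the fallback planned for normalized values was used in its place.

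The test was limma 3.58.1 in R 4.3.3, with statmod 1.5.0 for its robust version, on log2(value + 1), with variance moderation along the mean-variance trend and no replicate block. Genes entered the test with at least 10 normalized reads in at least 3 of the 6 libraries, which left 13052. Adjusted p-values are Benjamini-Hochberg values over these genes, and a gene was called at an adjusted p-value under 0.05. Fold changes are on the log2(value + 1) scale and understate the change of genes with low values. For a gene whose vehicle libraries are listed at 0, levels are given without a fold. Data for T3 against vehicle were also simulated for these genes, with 50 genes changed at each fold size, and 12928 genes passed the filter again. The test recovered 60% of genes changed by 1.25-fold, 78% by 1.5-fold, 86% by 2-fold and 98% by 4-fold, with filtered genes counted as missed. In that simulation 8 of 169 calls were genes with no change. Far fewer genes changed there than were called in the real data, and the scaling was known, so these rates need not carry over.

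A total of 37 gene lists were fixed before the data were examined, covering thyroid hormone response, intestinal cell types, signalling, metabolism, stress, immune genes and markers of other cell types. Lists with at least 5 tested members, 35 in all, were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over lists. Camera with an estimated correlation and fry, which tests a list without comparing it with other genes, were run beside it. Genes are named by a rule fixed at the same time. It takes the 10 largest rises and the 10 largest falls among called genes with a mean CPM of at least 1 and no overlap between groups, leaving out unnamed gene models. It adds up to 4 called members with the smallest p-value in each list, or up to 2 members with the highest mean CPM where none was called, the 10 called genes with the smallest p-value, and Thra, Thrb, Klf9, Hr, Dio1 and Lgr5. Genes named outside the rule are said to be so, and a few genes that the rule takes are not reported here.

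Alternatives were other scalings, filters on low values, pseudocounts, thresholds and variance models, a replicate block, leaving out each library, and removal of a trend on exon length and GC content. GC content came from GENCODE transcripts of GRCm38 matched by symbol, with a value for 96.6% of the genes tested. Genes that share sequence with close relatives, such as Acot1, Cyp3a44, H2-Q1, H2-Q2, Aldh1a1 and Aldh1a7, are uncertain, since the counting could have split their reads, and so are genes overlapping others on the opposite strand.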

Results

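The 6 libraries compared organoids from mouse small intestine after 17 h with T3, the active thyroid hormone, at 1e-07 M (3 libraries) or with vehicle (3 libraries). The study asked which transcripts respond to T3 in the intestinal epithelium. Column totals were 28197080 to 28611883 normalized reads in the vehicle libraries and 29510422 to 29974091 in the T3 libraries. The factors recovered from the low values put the reads behind them at an estimated 26100000 to 30800000 per vehicle library and 29700000 to 31100000 per T3 library. The mitochondrial genes, as listed, summed to 2.00% ± 0.219 of normalized reads with vehicle and 2.21% ± 0.369 with T3 (SD, n = 3), a difference within the spread of the libraries (exact permutation test, two-sided p = 0.4, smallest possible 0.1). This sum is not the full share of the mitochondrial genome, because COX2, COX3 and ATP6, chosen after their values were seen, were listed at means of 3.67, 9 and 1.33 with vehicle beside 203068 for COX1. Component 1 of a principal component analysis held 76.3% of the variance and separated the groups. Between replicate libraries the mean chi-square per gene ran from 4.89 to 14.9, above sampling noise in every pair, so each was kept as a separate library. The pairs with T3 replicate 3 were at 13.9 and 14.9 against 5.07 between T3 replicates 1 and 2, and those with vehicle replicate 1 at 8.13 and 9.92 against 4.89 between vehicle replicates 2 and 3. Levels are mean normalized reads ± SD with n = 3 per group, and where a list has no separate count adjusted over the list alone, that count was the same as over all genes.

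T3 changed the level of a large part of the transcriptome. Of 13052 genes tested, 5851 were called, 3135 higher and 2716 lower with T3. Most changes were small, with a median absolute log2 fold change of 0.35 among called genes, and 450 genes rose and 274 fell at least 2-fold. Changes of at least 8-fold were mostly rises, 50 against 6. The groups did not overlap at 7162 genes, or 54.9% of those tested, where chance gives 10%. The share of called genes that were higher was 53.6% with the deposited scaling, but 40.6% with upper-quartile scaling and 38.8% with equal column totals, so the balance of small rises and falls depends on the scaling. Of the authors' deposited table's 5055 calls at the same threshold, 5032 were among the genes tested, and 4982 of these were called here in the same direction. A further 869 genes were called here only. Both fits rest on the same 6 libraries, so this compares methods and is not independent evidence.

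**Figure D1:**
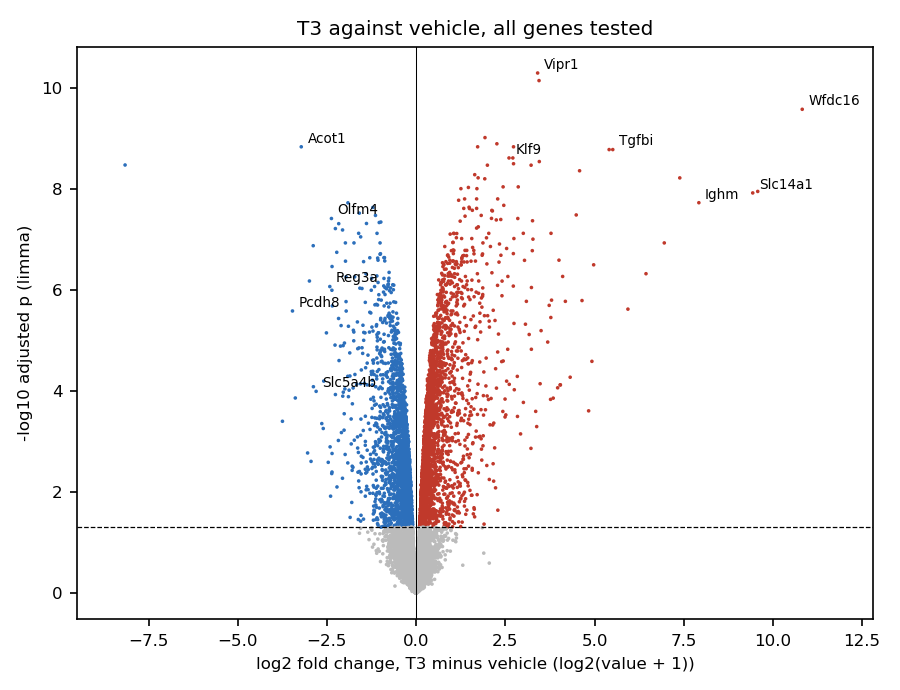
Each point is a gene tested, with the log2 fold change of T3 minus vehicle on log2(value + 1) on the horizontal axis and -log10 of limma's adjusted p on the vertical axis. Red points are the 3135 genes called higher, blue points the 2716 called lower and grey points those not called, and the dashed line marks an adjusted p of 0.05.

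The largest rises were in genes close to silent in vehicle libraries. Wfdc16, a whey acidic protein domain gene (gene ID 277345, GRCm38 chromosome 2, 164634708 to 164638802, 4 exons), was listed at 0 in the vehicle libraries and at 1894, 1943 and 1615 in the T3 libraries. Armc2 went from 0.333 ± 0.577 to 961 ± 36.5 and its neighbour on chromosome 10, Sesn1, a stress-induced regulator of growth signalling, rose 4.80-fold. Armc2 (41914990 to 42018382) lies downstream of the end of Sesn1 (41908436) on the opposite strand, so the genes point toward each other. The strand setting of the counting is not given, so reads running on past Sesn1 cannot be told from Armc2 transcripts. Slc14a1, a urea transporter (gene ID 108052, chromosome 18, 78100091 to 78142119), rose from 18.0 ± 7.81 to 12257 ± 801. Ighm, the constant region of the immunoglobulin mu heavy chain, was listed at 0 with vehicle and at 223, 272 and 234 with T3, and Cyp17a1, a steroid hydroxylase, was listed at 0 with vehicle and averaged 88.3 ± 24.5 with T3. Cyp3a44 rose from 1.00 ± 0 to 334.7 ± 3.21, Faim2 from 1.67 ± 1.15 to 312.7 ± 27.2, and Wfdc10 from 1.00 ± 1.00 to 111 ± 15.4. Among genes already expressed, Tgfbi, an extracellular matrix protein (gene ID 21810, chromosome 13, 56609603 to 56639339), rose 45.6-fold (log2 5.51 ± 0.12 SE) and Adh6a, an alcohol dehydrogenase, rose 42.5-fold (log2 5.41 ± 0.11 SE).

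Genes that fell strongly were of several kinds. Acot1, an acyl-CoA thioesterase (gene ID 26897, chromosome 12, 84009502 to 84017670), fell 9.32-fold from 4726 ± 174 to 507 ± 44.2. Pcdh8, a protocadherin, fell 11.1-fold, Emid1 7.96-fold, Tmem266 7.39-fold and Rims4 6.02-fold. Slc5a4b fell 6.99-fold, Ces1f, a carboxylesterase, 5.72-fold, and Reg3a, a secreted lectin, 5.35-fold. Olfm4, a marker of crypt stem cells, fell 5.19-fold from 27003 ± 2876. The smallest p-values belonged to Vipr1, a receptor for vasoactive intestinal peptide, which rose 10.6-fold from 852 ± 22.7 to 9035 ± 171 (adjusted p = 5.13e-11), and to Ppard, a nuclear receptor for fatty acids (chromosome 17, 28232754 to 28301469), which rose 10.9-fold (adjusted p = 7.25e-11). Rab43 rose 3.81-fold with an adjusted p of 9.73e-10.

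Genes known to respond to thyroid hormone were mostly higher. Klf9, a transcription factor directly induced by T3 in many tissues (gene ID 16601, chromosome 19, 23141226 to 23166911), rose 6.08-fold from 352 ± 20.3 to 2144 ± 60.8 (log2 2.60 ± 0.06 SE). Dio1, the deiodinase that converts T4 to T3, rose 3.21-fold, Cpt1a, which carries fatty acids into mitochondria, 3.30-fold, Bcl3 4.10-fold and G6pc, which releases glucose from its phosphate, 4.24-fold. Hr, a corepressor often induced by T3, fell 1.56-fold (adjusted p = 0.00333). In the list of thyroid hormone response genes, 13 of 21 tested members rose and 3 fell, or 14 and 4 adjusted over the list alone. The list was higher by camera (adjusted p = 0.000143, but adjusted p = 0.192 with an estimated correlation). Among receptors, transporters and cofactors 7 of 17 rose and 3 fell, or 7 and 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.462). The receptor gene Thra fell 1.66-fold, from 2582 ± 107 to 1555 ± 53.9, while Thrb stood at 1573 ± 65.7 and 1446 ± 69.1 (adjusted p = 0.0848, but 0.0162 with upper-quartile scaling and 0.0298 without T3 replicate 3). The hormone transporter Slc16a10 rose 2.56-fold and Ttr, a carrier of thyroid hormone in blood, fell 3.35-fold.

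**Figure D2:**
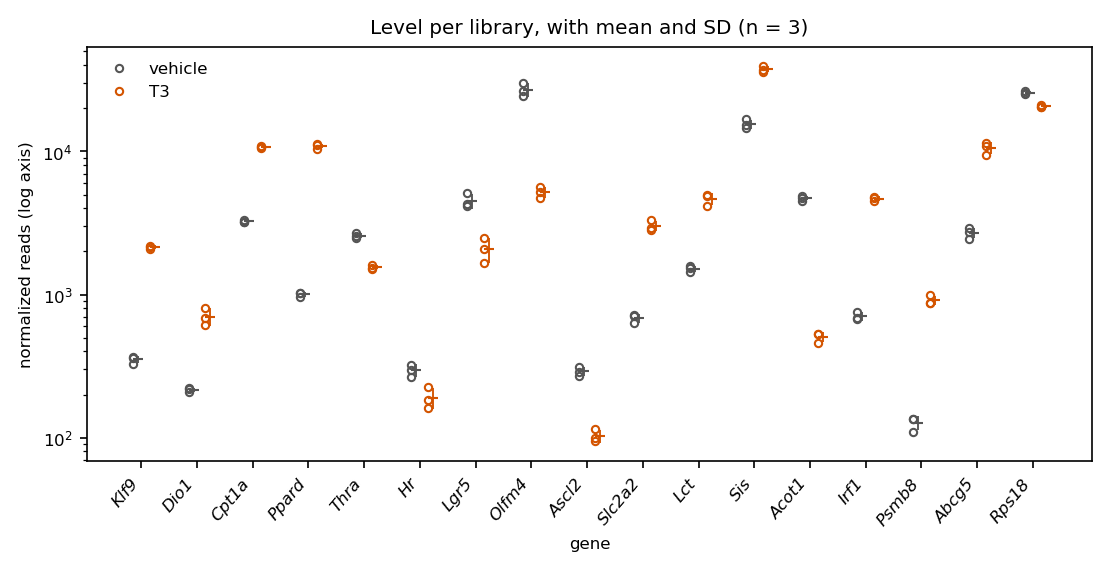
Normalized reads per library on a log axis for 17 genes named in the text, with open circles for libraries and a bar with its error for the mean and SD of 3 libraries. The groups are apart for every gene drawn, from Klf9 at 352 and 2144 to Rps18 at 25822 and 20748.

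The list of Lgr5 stem cell genes was lower and that of enterocyte genes higher. Of 24 tested members of the Lgr5 stem cell list 13 fell and 3 rose, or 13 and 4 adjusted over the list alone, with a median log2 fold change of -0.51 (camera adjusted p = 0.000549, but adjusted p = 0.514 with an estimated correlation). Lgr5, the receptor that marks cycling crypt stem cells (gene ID 14160, chromosome 10, 115450314 to 115587780), fell 2.19-fold from 4506 ± 514 to 2073 ± 406. Igfbp4 fell 2.78-fold, Aqp4 1.73-fold and Ephb3 1.72-fold. In the list of reserve stem cell genes, which did not pass (adjusted p = 0.0879), Mex3a fell 2.16-fold, Tert 2.03-fold and Bmi1 1.24-fold, and Krt19 rose 1.13-fold, a rise not called with upper-quartile scaling or without single libraries. Of 30 enterocyte genes 19 rose and 5 fell, or 19 and 6 adjusted over the list alone, with a median log2 fold change of 0.42 (camera adjusted p = 0.000913, but adjusted p = 0.535 with an estimated correlation). Slc2a2, the basolateral glucose and fructose transporter, rose 4.40-fold, Lct, the lactase gene, 3.07-fold, Sis, sucrase-isomaltase, 2.42-fold to 37607 ± 1930, and Slc5a1, the sodium-glucose transporter, 2.23-fold.

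Of 3 signalling lists, Notch pathway genes and Wnt targets were lower as lists at the preset correlation, and BMP and hedgehog genes did not pass. Among Notch pathway genes 9 of 18 fell and 1 rose (camera adjusted p = 0.00515, but adjusted p = 0.259 with an estimated correlation). Lfng fell 2.24-fold, Notch1 1.72-fold, Dtx4 1.57-fold and the Notch target Hes1 went from 3100 ± 67.7 to 2489 ± 89.6. Of 19 Wnt target genes 6 fell and 2 rose (camera adjusted p = 0.038, but adjusted p = 0.45 with an estimated correlation, and 0.0559 at the preset correlation without vehicle replicate 3). Ascl2, a stem cell transcription factor, fell 2.81-fold and Myc 1.64-fold. All fallen Wnt targets except Myc (Ephb3, Ascl2, Lgr5, Axin2 and Sox9) are also in the Lgr5 stem cell list. The Wnt result is therefore not separate from the result of that list. Among Wnt targets outside it, Myc fell while Ccnd1 and Sp5 rose. Axin2, Sox9, Ccnd1 and Sp5 are named outside the rule. BMP and hedgehog genes went both ways, 4 higher and 5 lower of 12, with a median of -0.09 and a mean of 0.06, and the list did not pass (adjusted p = 0.66). In it Id3 rose 2.53-fold while Smad6 fell 3.78-fold, Bmp7 1.52-fold and Ptch1 1.37-fold.

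Markers of secretory cells and tuft cells went both ways or did not pass as lists, except for enteroendocrine genes. For Paneth cell genes 4 of 19 rose and 4 fell (adjusted p = 0.873), with Itln1, an intelectin, 2.49-fold higher at 80652 ± 8932, Mptx1 2.17-fold higher, Pnliprp2 1.71-fold lower and Fgfrl1 1.55-fold lower. For goblet cell genes 1 of 23 rose and 3 fell (adjusted p = 0.408), with Clca1 2.83-fold higher and Foxa3 1.39-fold, Galnt12 1.43-fold and St6gal1 1.63-fold lower, the last a call lost without single libraries. Of 30 enteroendocrine genes 4 fell and none rose, or 2 and none adjusted over the list alone (camera adjusted p = 0.0489, but adjusted p = 0.744 with an estimated correlation, and 0.111 with upper-quartile scaling). The enteroendocrine call was also lost without vehicle replicate 2 (0.236), vehicle replicate 3 (0.0719) and T3 replicate 3 (0.507), and without the last the list median was 0.00921. Cplx2 fell 1.79-fold and Neurog3, the factor that specifies these cells, 1.27-fold, and the calls of Insm1 and Fev, also lower, were lost without single libraries. Of 16 tuft cell genes 5 fell and none rose, or 4 and none adjusted over the list alone (adjusted p = 0.136), among them Pou2f3, the tuft cell regulator, 1.81-fold, Ptpn6 1.30-fold, Il17rb 1.56-fold and Cd24a 1.13-fold, and the calls of Il17rb and Cd24a were lost without single libraries.

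Genes of the fetal-like and regenerative list rose in 12 of 17 cases and fell in 1, or 14 and 1 adjusted over the list alone (camera adjusted p = 0.00121, but adjusted p = 0.535 with an estimated correlation). Il33, an alarmin, rose from 9 ± 3 to 133.7 ± 5.69, Tnfrsf12a 1.80-fold and Reg3b 1.66-fold, while Cnn3 fell 2.10-fold.

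Markers of other cell types were mostly near 0. Only 2 fibroblast and smooth muscle markers were tested, Vim at 247 ± 48.4 and 218 ± 40.1 and Pdgfrb at 84.0 ± 14.4 and 70.7 ± 7.09, and neither was called. Of immune markers only Itgam and Cd68 were tested, and Itgam rose 3.59-fold to 349 ± 7.55, while Ptprc, chosen after its values were seen, averaged 0.333 and 1.33. Of 6 endothelial, neural and blood markers Lyve1 alone was called, 1.29-fold lower (adjusted p = 0.0478), a call lost adjusted over the list alone, in 5 of the 6 sets without a library and with a replicate block, and the list did not pass (adjusted p = 0.114). Of 5 stomach and colon markers Atp4a fell 1.89-fold and Pgc rose 3.46-fold (list adjusted p = 0.898).

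**Figure D3:**
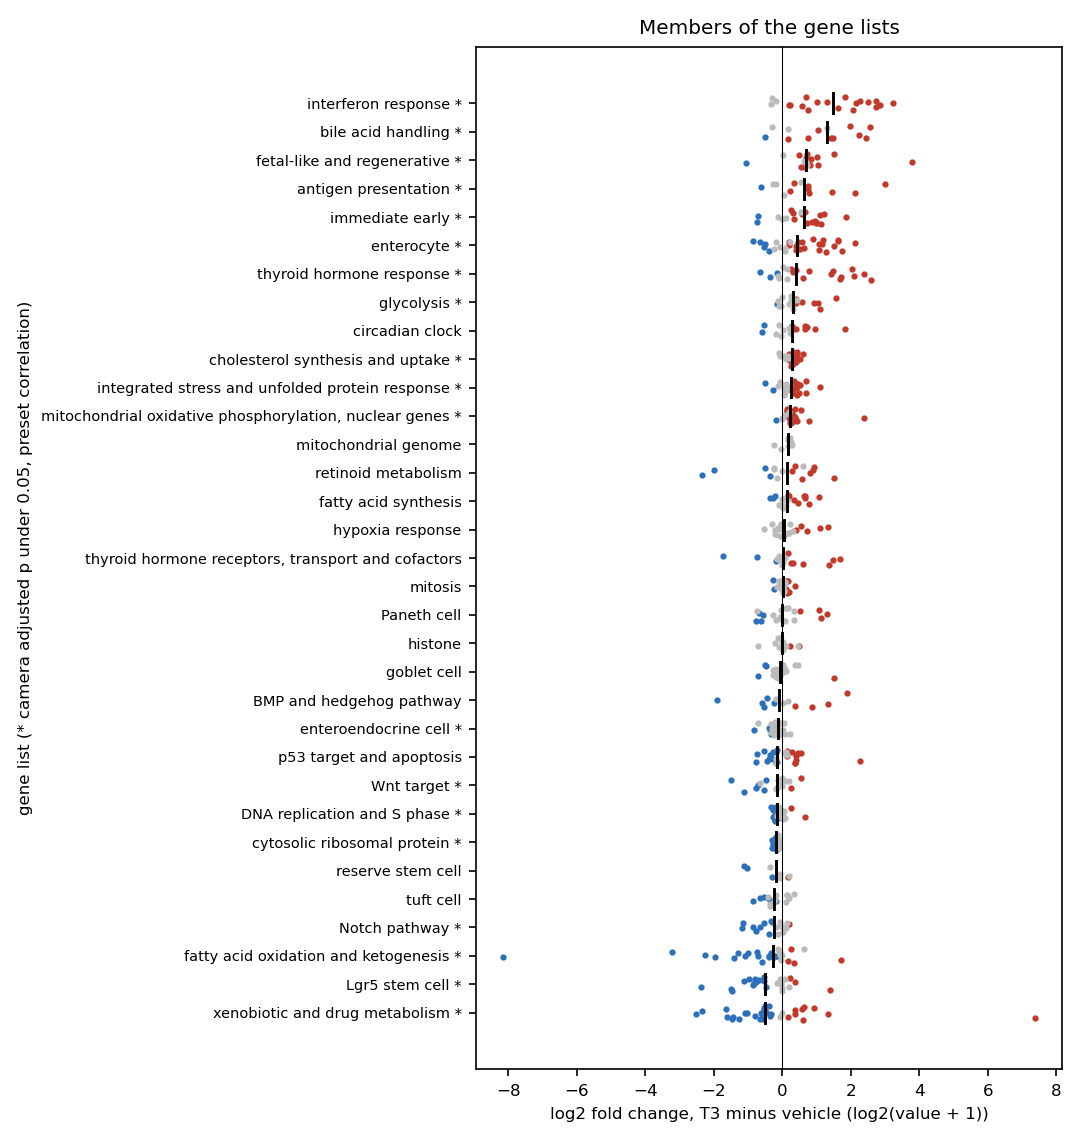
Each point is a tested member of a gene list, placed by its log2 fold change of T3 minus vehicle, red if called higher, blue if called lower and grey if not called, and black bars are list medians. Lists are ordered by median, from interferon response at 1.47 to xenobiotic metabolism at -0.52, and a star marks lists with a camera adjusted p under 0.05 at the preset correlation.

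Lipid genes split by pathway. Of 29 genes of fatty acid oxidation and ketogenesis 17 fell and 4 rose, or 19 and 4 adjusted over the list alone, with a median log2 fold change of -0.28 (camera adjusted p = 8.3e-06, but adjusted p = 0.514 with an estimated correlation). Beside Acot1, Angptl4, a secreted lipase inhibitor, fell 4.81-fold, and Cpt1a of the same list rose. Of 25 genes of cholesterol synthesis and uptake 18 rose and none fell, or 19 and none adjusted over the list alone (camera adjusted p = 2.16e-05, but adjusted p = 0.537 with an estimated correlation). These rises were small, 1.51-fold for Msmo1, 1.44-fold for Sc5d and 1.33-fold for Sqle. Fatty acid synthesis genes rose in 9 of 20 cases and fell in 3, or 10 and 3 adjusted over the list alone, without passing (adjusted p = 0.0584, but 0.0118 without T3 replicate 3 and 0.0299 with no filter on low values), and Elovl6 rose 2.08-fold, Mlxipl 1.70-fold, Agpat2 1.58-fold and Elovl5 1.55-fold. Bile acid and sterol handling genes rose in 9 of 13 cases and fell in 1 (camera adjusted p = 0.000549, but adjusted p = 0.259 with an estimated correlation). The sterol exporters Abcg5 and Abcg8 rose 3.92-fold and 2.66-fold, Abca1 2.77-fold and the bile acid exporter subunit Slc51a 5.93-fold.

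Of 34 xenobiotic and drug metabolism genes 23 fell and 9 rose. The median log2 fold change was -0.52 and the mean -0.28. Camera placed the list lower (adjusted p = 0.000914, but adjusted p = 0.535 with an estimated correlation), whereas fry placed it higher (fry adjusted p = 0.00521). The transporters Abcc3 and Abcc2 fell 1.73-fold and 1.55-fold, and Cyp3a25 rose 1.92-fold. Retinoid genes went both ways, 7 higher and 4 lower of 16, or 8 and 4 adjusted over the list alone (adjusted p = 0.593). Aldh1a1 and Aldh1a7, enzymes of the retinaldehyde dehydrogenase family, fell 5.10-fold and 3.96-fold, while Dhrs9 rose 2.86-fold and Bco2 1.76-fold.

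Nuclear genes of oxidative phosphorylation were higher. Of 35 nuclear genes of oxidative phosphorylation and its regulators 30 rose and 1 fell, or 31 and 1 adjusted over the list alone, with a median log2 fold change of 0.23 (camera adjusted p = 5.89e-08, but adjusted p = 0.516 with an estimated correlation). Ppargc1a, the coactivator of mitochondrial biogenesis, rose 5.19-fold, Cycs, the cytochrome c gene, 1.72-fold, Cox5a 1.45-fold and Sdhd 1.31-fold. Of 8 tested members of the mitochondrial genome list, which left out 5 members near 0, 0 were called by limma, and 0 had an unadjusted p under 0.05 (list adjusted p = 0.458), with COX1 at 203068 ± 29015 and 229531 ± 35591 and CYTB at 109151 ± 8786 and 127968 ± 21595. Without T3 replicate 1 that list passed (adjusted p = 0.0389) and CYTB was called higher. Glycolysis genes rose in 7 of 19 cases and fell in 1 (camera adjusted p = 0.0205, but adjusted p = 0.744 with an estimated correlation), a call lost at the preset correlation without T3 replicate 1 (0.057) or T3 replicate 2 (0.0801). Hk2 rose 2.98-fold, Pfkfb3 2.16-fold, Pfkp 2.07-fold and Pkm 1.89-fold. For each of them T3 replicate 3 was the lowest T3 library. Pfkfb3 stood at 4186, 4563 and 2453 in T3 replicates 1 to 3 against 1670 ± 72.0 with vehicle. Hypoxia response genes rose in 5 of 19 cases, or 3 adjusted over the list alone (adjusted p = 0.438, but 0.000325 without T3 replicate 3). Ankrd37 was 2.51-fold, Epas1 2.15-fold and Higd1a 1.64-fold higher. A rise of Car9, 1.45-fold, was lost in 5 of the 6 sets without a library. T3 replicate 3 was again the lowest T3 library for each. In T3 replicates 1 to 3 Ankrd37 stood at 1731, 2044 and 880 (vehicle 583 ± 48.5). Car9 stood at 7550, 8130 and 4535 (vehicle 4501 ± 79.9).

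Genes of protein synthesis and the cell cycle moved little. Of 40 cytosolic ribosomal protein genes 31 fell and none rose, or 34 and none adjusted over the list alone, with a median log2 fold change of -0.18 (camera adjusted p = 5.84e-08, but adjusted p = 0.535 with an estimated correlation). Rps18 fell 1.24-fold from 25822 ± 721 to 20748 ± 469, Rpl22 1.22-fold, Rpl14 1.21-fold and Rpl10a 1.20-fold. Of 30 DNA replication genes 16 fell and 2 rose (camera adjusted p = 0.00737, but adjusted p = 0.723 with an estimated correlation). Msh6 fell 1.26-fold, Uhrf1 1.20-fold and Mcm6 1.18-fold, while Rrm2, the ribonucleotide reductase subunit, rose 1.58-fold. Of 30 mitosis genes 7 rose and 2 fell, or 4 and 2 adjusted over the list alone (adjusted p = 0.577), with Ube2c 1.31-fold and Anln 1.13-fold higher and Kif20a 1.22-fold and Ttk 1.18-fold lower. Of 14 histone genes 2 rose, Hist1h2bc 1.41-fold and H1f0 1.17-fold (list adjusted p = 0.873).

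Interferon response and antigen presentation genes were mostly higher. Of 20 interferon response genes 17 rose and none fell, with a median log2 fold change of 1.47 (camera adjusted p = 6.62e-07, but adjusted p = 0.142 with an estimated correlation). Irf1, a transcription factor of the interferon response, rose 6.63-fold from 706 ± 48.3 to 4681 ± 164, the immunoproteasome subunit Psmb8 7.21-fold, Oasl2 4.86-fold and Ifih1 2.02-fold. Antigen presentation genes rose in 9 of 14 cases and fell in 1 (camera adjusted p = 0.000243, but adjusted p = 0.516 with an estimated correlation). H2-Q1 rose 8.02-fold, H2-Q2 4.32-fold, Tapbp 2.76-fold and B2m 1.68-fold, and the H2-Q genes share sequence with one another.

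Stress and early response genes were mostly higher. Integrated stress and unfolded protein response genes rose in 19 of 30 cases and fell in 2, or 20 and 2 adjusted over the list alone (camera adjusted p = 0.000224, but adjusted p = 0.535 with an estimated correlation). Edem1 rose 1.61-fold, Chac1 1.60-fold and Manf 1.42-fold, while Phgdh, an enzyme of serine synthesis, fell 1.42-fold. Immediate early genes rose in 14 of 20 cases and fell in 2, or 15 and 2 adjusted over the list alone (camera adjusted p = 0.00121, but adjusted p = 0.516 with an estimated correlation), with Fos 3.66-fold and Klf6 1.97-fold higher and Btg2 1.68-fold lower. Genes of p53 targets and apoptosis went both ways, 10 higher and 12 lower of 27, or 10 and 13 adjusted over the list alone, with a median of -0.15 and a mean of 0.03 (adjusted p = 0.734), and Mdm2 rose 1.29-fold while Trp53inp1 fell 1.37-fold. Clock genes rose in 9 of 17 cases and fell in 2, or 10 and 2 adjusted over the list alone (adjusted p = 0.0808, but 0.0118 without T3 replicate 3 and 0.0428 with equal column totals), with Hlf 3.53-fold, Cry1 1.58-fold and Arntl 1.31-fold higher, while Tef went from 1241 ± 63.6 to 826.7 ± 82.0.

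Of the 35 lists tested, 19 passed camera at the preset correlation, 11 higher and 8 lower, and fry called 21 as moving on balance in a single direction. These were not all the same lists. DNA replication (fry adjusted p = 0.169), enteroendocrine (0.238) and glycolysis genes (0.0901) passed camera only. Reserve stem cell, fatty acid synthesis and p53 target genes passed fry only. So did thyroid hormone receptors, transport and cofactors, and endothelial, neural and blood markers. The xenobiotic list passed both in opposite directions. With a correlation estimated from the 6 libraries 0 passed camera, and 4 had an unadjusted p under 0.05, so the comparison of a list with other genes rests on the preset value, whereas the calls of single members do not use it.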

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

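Counts of called genes stayed within 1.5 times the reported 5851 under other scalings, filters, pseudocounts, variance models, p thresholds and left-out libraries (4057 to 6855), and fell to 1648 when a 1.5-fold change was also required, a condition that by construction admits fewer genes. The filter at 50, equal column totals, the variance model without a trend, vooma weights and removal of the length and GC trend were chosen after seeing the data. Of the 5851 genes 89.4% were called again with upper-quartile scaling, 88.2% with equal column totals and 76.9% to 92.5% without a library. The share of calls that were higher, 53.6%, was 40.6% with upper-quartile scaling, 38.8% with equal totals, 56.8% at an adjusted p under 0.01, 52% under 0.1, 57.0% with the 1.5-fold condition and 53.7% to 55.2% without a library. Both scalings lower T3 values relative to vehicle, and the median log2 fold change of all genes went from -0.01 to -0.06 and -0.07. Shared calls with the authors' deposited table were 4982, then 1491 with the 1.5-fold condition here and 1404 when the authors' calls were held to it. With an estimated correlation 0 lists passed camera against 19, and the cause was not tested. No called list changed camera's direction under the alternatives run, though the enteroendocrine median did without T3 replicate 3. Endothelial, neural and blood markers passed with no filter (adjusted p = 0.0491). Without single libraries the adjusted p of called genes rose to at most 0.129 for Lyve1, 0.123 for Car9, 0.101 for Fev, 0.0731 for Cd24a, 0.0701 for Insm1, 0.0629 for St6gal1, 0.0621 for Krt19 and 0.0592 for Il17rb, and no other named gene lost its call. Among lists that were not called, camera's direction reversed from higher to lower for mitosis (median -0.0366 with upper-quartile scaling and -0.0469 with equal totals). It reversed from lower to higher for Paneth cells (medians -0.0536, -0.0638 and, with no filter, 0.0455, against 0.00245 as reported). The same reversal was seen for stomach and colon markers (0.058, 0.0478 and 0.195, against 0.114). Camera sets a list against other genes, so its direction need not match the sign of the median. Without single libraries medians ran from -0.00959 to 0.0333 for histones, -0.109 to 0.172 for Paneth cells, -0.102 to 0.158 for stomach and colon markers and -0.155 to 0.0726 for goblet cells, and the cause was not tested. Labels give both groups replicate numbers 1 to 3, but deviations of same-numbered libraries correlated at -0.07, 0.03 and -0.06, and not every library correlated best with its own number. These values gave no sign that the numbers pair the libraries, but values so near 0 cannot exclude a pairing. A replicate block called 5405 genes, 2933 of them higher. The planned count tests and voom were not run, because the values are not counts, and median-of-ratios scaling was not run, because the values already carry a scaling. At depths of an estimated 26100000 to 31100000 reads, the filter at 10 normalized reads left lower genes untested. Without that filter 18173 genes were tested.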

Other observations

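Gene families defined by their symbol stem, an approach chosen after the values were seen, added further groups, several of which share members with the fixed lists. Psmb8, for example, is in the interferon response list, and Slc2a2 and Slc5a1 are in the enterocyte list. Of 199 families with at least 8 tested members, 15 passed camera at the preset correlation and 0 with an estimated one, where 3 had an unadjusted p under 0.05. The medians of these 15 kept their sign under 3 scalings. All 10 carboxylesterase genes (Ces) fell, with a median log2 fold change of -1.04 (camera adjusted p = 1.26e-05, and adjusted p = 0.78 with an estimated correlation), though its members share sequence and some are in the xenobiotic list. Of 337 zinc finger genes named Zfp, 100 fell and 19 rose (median -0.12, adjusted p = 0.00406), and of 8 Cbx genes, which encode chromobox proteins, 5 fell and none rose (median -0.23, adjusted p = 0.0332). Of 257 solute carrier genes (Slc) 106 rose and 38 fell (median 0.14, adjusted p = 0.0088), of 17 myosin genes (Myo) 11 rose and 1 fell (median 0.27, adjusted p = 0.00406), and of 10 proteasome beta subunit genes (Psmb) 8 rose and none fell (median 0.16, adjusted p = 0.0088). Of 25 Sec genes, many of them in the secretory pathway, 14 rose and 1 fell (median 0.13, adjusted p = 0.0088). With an estimated correlation the adjusted p was 0.78 for each of these families.

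The tests on Ighm, the scaling test on ribosomal genes and the test on divergent neighbours were chosen after the values they rest on were seen, and the tests on neighbours, on length and GC content and on splits before their results, although single raised neighbours had been seen. Ighm was listed at 0 in the 3 vehicle libraries and averaged 243 ± 25.7 with T3 (SD, n = 3). B cells or plasma cells would bring their light chain and joining chain transcripts, but Igkc, Jchain, Mzb1, Cd79a, Cd79b and Ms4a1 together averaged 4 with T3 and 5 with vehicle, 1.65% of the Ighm level. Opening of the wider locus could raise its other genes. Of the 13 genes within 200 kb that have at least 200 bp of exons, 0 rose above the vehicle libraries to 10 normalized reads, and the 14 shorter ones were left out. These 13 were other immunoglobulin genes, Adam6a and Adam6b, listed at 0 or 1 in every library. Whether an open locus would raise them in epithelium is not known from these data, so they cannot decide this. An Ighm transcript made in the epithelium itself under T3 may remain as an explanation, and its structure, or reads from elsewhere assigned to Ighm, were not tested.

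Genes beside strongly raised genes were often raised themselves. Of 647 pairs of a gene raised at least 2-fold and a nearest neighbour within 100 kb, 40.96% had the neighbour called higher. The central 95% of 1000 draws matched on expression ran from 20.7% to 27.4%. Counts here are of pairs, so a neighbour can count more than once, and adjacent raised genes count in both directions. The draws took only genes outside the raised set, so they hold no such double counts and may understate the spread. With neighbours of the same symbol stem left out, 38.3% were still called higher (matched draws 21.1% to 27.9%), so copies sharing a stem do not account for the excess. Related copies with other stems stayed in, and read sharing among them was not tested. Reads running on past the end of the raised gene would not reach divergent neighbours, which start beside it on the opposite strand and point away. Yet 47.2% of 127 of these were called higher (matched draws 17.2% to 30.5%). This argues against run-on for divergent neighbours, though some adjacent raised genes count in both directions. For the other neighbours run-on stays open, since the strand setting of the counting is not given and an upstream gene could itself run on into the raised gene, so the comparison of same-strand downstream neighbours (37.0% of 138) with all others (38.7% of 445; Fisher's exact test, two-sided p = 0.764) cannot decide. Regulation shared by neighbouring genes, as at Duox2 and Duoxa2, a divergent pair chosen after its values were seen, may be a candidate and was not tested further.

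Ribosomal protein genes fell while nuclear oxidative phosphorylation genes rose, with list medians 0.41 apart on the log2 scale. A scaling error of 1 factor per library moves every gene of a library alike and leaves the gap within it unchanged. That gap was larger with T3 by 0.398 ± 0.018 (SE over libraries, n = 3 per group). The value restates the list medians already seen and is not separate evidence, and it does not exclude a shift common to both lists. The ribosomal and oxidative phosphorylation medians were -0.233 and 0.175 with upper-quartile scaling, and -0.243 and 0.164 with equal column totals. A trend on exon length or GC content would shrink the gap when removed, but it was 0.408 ± 0.025 before and 0.412 ± 0.026 after removal (bootstrap SE over members), and 0.406 ± 0.023 after removal within libraries (SE over libraries). A response to T3 in the balance of these gene groups may be the explanation, as a hypothesis, and a change in the mixture of crypt and absorptive cells is another that bulk values leave untested.

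The count of 5851 called genes was compared with the other 9 splits of the 6 libraries into 3 and 3. With limma the highest count in another split was 0, with at most 316 genes at an unadjusted p under 0.05 against 6798 in the real split, and 1 of 10 splits, the real one, gave a count as large. Each other split mixes T3 and vehicle libraries in both groups, so the T3 difference widens the spread within groups and low counts were assured. The other splits therefore do not show what count would arise without a T3 effect. A total of 10 splits is too few for a share under 0.05.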
